A study of Mus musculus with 8 samples.

How the data were processed

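Motor cortex cells of female mice were profiled in 4 groups, wild type and Gsdmd-/- after PBS or LPS. Libraries were made with single cell 3' v3.1 chemistry from 10x Genomics, per the labels' protocols, after papain dissociation and sorting. Per the submitters' processing notes, reads were processed with Cell Ranger 6.0.1 on the mm10 genome. The gene annotation and the cell calling settings are not given in the sources used here. The values deposited by the authors are UMI counts per gene and barcode, without normalization, per the file headers, for 31053 genes. The authors' cell table gives a class, a subtype, a UMI count and a mitochondrial percent for each cell they kept. Those UMI counts were lower than the matrix totals, at a median of 97.9%, 96.1%, 97.9% and 97.7% of them in the 4 groups, and the matrix counts were used.

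The labels name 8 entries in 4 groups, 2 per group on different sequencing platforms. The matrices pool the entries of a group and nothing maps cells to entries, so each group was 1 library, no p-value was computed and cells were not treated as replicates. Of 33587 barcodes, 23361 carry the authors' annotation and 10226 do not. Classes (7) and subtypes (20) were taken from the authors, without further filter on cells. Annotated cells had at most 5.99%, 5.76%, 5.52% and 6.95% mitochondrial UMIs. No doublet caller was run, and whether doublets were removed before deposit is not given in the sources used here. Mixed cells were instead left out in alternatives.

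UMIs were summed per group and class and expressed as CPM of the class total. Folds are log2((CPM + 5)/(CPM + 5)), which understates the change of low genes. A gene was compared in a class with at least 20 UMIs over the 4 libraries and at least 50 CPM in at least 1 of them. Counts have exact Poisson intervals, ratios of sums exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95%. Intervals of log2 folds, list medians and differences are from 1000 Poisson redraws. All of them cover counting error only. A count of 0 is redrawn as 0 each time, so intervals from redraws are too narrow where a gene or list members had no UMI in a library. A fold against 0 UMIs is given as a bound against 3 counts per library, and no fold is given where both counts are at most 3. The difference of folds is wild type minus knockout. List medians were placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. The size of the response was compared after sampling each class and library to the same number of UMIs.

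The groups, the comparisons, 22 cell type marker lists, 29 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule left out mitochondrial, ribosomal protein, haemoglobin, Gm and Rik genes, and genes more than 5 times higher in another class. In endothelial cells it took the 10 highest and 10 lowest genes by the smaller fold of the genotypes, the 8 most positive and 8 most negative differences, and the 5 highest and 5 lowest in knockout under both treatments. In the other classes, each with at least 100 cells per group, it took 4, 3, 2 and 2 genes by the same measures of response and difference, and from each list up to 4 members with the greatest absolute fold in wild type. Gsdmd, Casp4, Tlr4, Cd14 and Cldn5 were always included. Genes with at most 3 UMIs in both libraries of a contrast were also left out of the ranking, a condition that is not part of that rule and was added later because no fold is given for them. Cxcl11, Mx2, Irgb10 and Irg1 are not among the symbols of the matrices. Single-gene values of 3 genes that the rule names are not reported here, and these genes stay members of their lists. Where a symbol has more than 1 identifier, the identifier with more UMIs was read.

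The authors' subtypes were checked against the marker lists, by asking whether the 10 leading genes of a subtype held more markers of another class than of its own. With the other subtypes as reference, 2 of 20 failed, committed oligodendrocyte precursors (led by the precursor markers Gpr17 and Neu4) and layer 6 corticothalamic neurons (with the B cell marker Ighm). With the other classes as reference, which was chosen after that result was seen, 0 of 20 failed. Values for the oligodendrocyte lineage and for excitatory neurons are therefore given with caution, and both classes were also computed without those subtypes. Endothelial cells are not subdivided in the annotation, so capillary cells were not compared alone.

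The alternatives were median-of-ratios scaling, a pseudocount of 1 CPM, no filter on low genes, a filter on cells (1000 to 40000 UMIs and at most 10% mitochondrial), the mean of CPM per cell, cells thinned to 1000 UMIs, totals without mitochondrial, ribosomal and haemoglobin genes, and mixed cells left out. Those chosen after seeing the data left out the top cell of each gene, cells with more UMIs of another marker list than of their own, and the subtypes named above, or took class shares over all barcodes, adding those of at least 500 UMIs without annotation and with 20 or more marker UMIs of the class per 10000. On simulated counts for endothelial cells, LPS against PBS in wild type, with 5037 genes of which 200 were changed, median recovered log2 folds were 0.96 for genes changed by 1 and 1.92 for genes changed by 2, the counting intervals held the true value for 98% and 97% of them, and 4.5% of 200 random lists lay outside the central 95%. The simulated counts were Poisson draws without spread between cells or animals, so they check the computation and not whether the intervals cover such spread. The intervals checked were the exact ones of ratios of sums, after allowing for the shift in the total that the changed genes made. Intervals from redraws were not checked. Expression was averaged over the 4 libraries, so genes without UMIs under PBS alone were not imitated. Coordinates are from GENCODE on GRCm38. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.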

Results

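Single cells were dissociated from the motor cortex of female wild-type and Gsdmd-/- mice of 6 to 8 weeks, about 8 hours after an intraperitoneal injection of PBS or 40 mg/kg lipopolysaccharide (LPS), the endotoxin of the outer membrane of Gram-negative bacteria. Gsdmd encodes gasdermin D, the pore-forming protein that inflammatory caspases cleave during pyroptosis. The series title places the question in brain endothelium, and asks about the part of gasdermin D in the breakdown of the blood-brain barrier during inflammation. The labels list 8 entries, 2 for each combination of genotype and treatment, which differ in the sequencing platform. Counts were given as 1 pooled matrix per combination, so each group is 1 library and there is no replicate spread and no test. Wild type under PBS held 9429 barcodes and 282576963 UMIs, wild type under LPS 7158 barcodes and 182170700 UMIs, knockout under PBS 8000 barcodes and 236176964 UMIs, and knockout under LPS 9000 barcodes and 333922018 UMIs. The authors annotated 7250, 3939, 5460 and 6712 of these barcodes, with median depths of 29419.5, 36071, 34069 and 40651.5 UMIs. Endothelial cells numbered 63, 99, 92 and 51, with 733522, 1119259, 917045 and 785209 UMIs in all. Intervals below are 95% intervals that cover counting error only, not differences between animals or preparations. Pairs of values after a gene or list are log2 folds of LPS over PBS in wild type and knockout. A difference of folds is wild type minus knockout, followed by its interval.

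Gsdmd stood highest in CPM in microglia and endothelial cells. Endothelial cells held 9 UMIs in wild type under PBS, 21 in wild type under LPS, 6 in knockout under PBS and 2 in knockout under LPS, which correspond to 12.3 (5.61 to 23.3), 18.8 (11.6 to 28.7), 6.54 (2.40 to 14.2) and 2.55 (0.308 to 9.20) CPM, the UMI count scaled by the total of the class in that library. Microglia held 64, 38, 30 and 7 UMIs, or 24.6, 9.59, 16.4 and 2.95 CPM. Astrocytes held 5, 1, 1 and 22 UMIs and oligodendrocyte precursors 0, 0, 0 and 8, so the highest value in each of these classes was in the knockout library under LPS. Oligodendrocyte lineage cells held 0 UMIs in all 4 libraries, which allows up to 0.178, 0.222, 0.359 and 0.313 CPM at 3 counts. Excitatory neurons held 1, 3, 4 and 3 UMIs and inhibitory neurons 0, 2, 0 and 0. Gsdmd (ENSMUSG00000022575) lies on chromosome 15 from 75862327 to 75867408 of GRCm38, on the plus strand. The part deleted in the knockout is not given in the sources used here and a 3' tag can lie outside it, so these counts do not check the genotype labels.

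Inflammatory genes were higher under LPS in endothelial cells of both genotypes, and most blood-brain barrier transporter genes were lower. Leukocyte adhesion and NF-kB target genes, acute phase genes and metallothioneins were higher, as were most chemokines and cytokines, and most genes of the transporter list and of the Wnt and identity list were lower. Across 5037 compared genes the log2 folds of the genotypes had a Pearson r of 0.88 and a Spearman rho of 0.84, with 82.9% of genes in the same direction; genes are not independent replicates. All 18 members of the endothelial activation list that passed the filter on low genes were at least 2-fold higher in each genotype. That filter can favour members raised by LPS, and without it the knockout median was 3.40. With the filter the median log2 fold was 3.67 (3.45 to 3.97) in wild type and 3.67 (3.47 to 3.90) in knockout. With members that had no UMI under PBS set at their lower bound, the medians were 3.75 and 3.89. Icam1, the receptor for leukocyte integrins, went from 17.7 to 1396 CPM in wild type and from 14.2 to 861 CPM in knockout. Csf3, the granulocyte growth factor, was at least 832-fold higher in wild type and at least 1761-fold higher in knockout, against 0 UMIs under PBS and a floor of 3 counts per library. Ch25h, the cholesterol 25-hydroxylase, was at least 181-fold higher in wild type and 1081-fold (194 to 42762) higher in knockout, where 1 UMI was counted under PBS. E-selectin (Sele) was at least 59.9-fold higher in wild type and at least 14.4-fold higher in knockout, where 54.1% of the UMIs sat in 1 cell. The all-gene median was -0.40 in wild type and -0.42 in knockout, and folds are best read against it. Alongside these genes, astrocyte markers in the endothelial sums went from 200.4 to 1027 CPM in wild type and from 230.1 to 962 CPM in knockout. Single cells carried most UMIs of some other lists. For erythroid markers, 1 cell held 4576 of 4578 UMIs in wild type and 5337 of 5410 in knockout under PBS, and for B cell markers 1 cell held 67 of 70 in knockout under LPS.

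Acute phase and metallothionein genes were higher in both genotypes. Their list medians were 3.94 (3.57 to 4.34) and 4.14 (3.86 to 4.47), or 3.94 and 4.39 with members without UMIs under PBS at their bound, with all 12 compared members at least 2-fold higher in each genotype. Lcn2, the siderophore-binding lipocalin, went from 2 UMIs to 12944 CPM in wild type, 4747-fold (1314 to 39205) higher, and from 1 UMI to 17338 CPM in knockout, 15899.8-fold (2853 to 628053) higher. Excitatory neurons of the same libraries carried 8.53 and 2.82 CPM of Lcn2. The metallothioneins Mt2 and Mt1, which bind zinc and copper, had log2 folds of 8.93 and 7.60 and of 7.76 and 6.35 in wild type and knockout. Ptgs2, the inducible cyclooxygenase, was 265-fold (90.5 to 1288) higher in wild type and 405-fold (138 to 1968) higher in knockout, from 3 UMIs in each PBS library. The prostaglandin list, with 3 compared members, had medians of 2.98 and 2.85. Of the chemokine list, 10 of 12 compared members in wild type and 9 in knockout were at least 2-fold higher, with medians of 4.23 (3.94 to 4.67) and 3.19 (3.01 to 3.61). Setting members without UMIs under PBS at their bound gave 4.34 and 4.85, so the order of the genotypes depends on how these members are treated. The neutrophil chemokine Cxcl1 was 528-fold (181 to 2564) higher in wild type and at least 939-fold higher in knockout, and Cxcl2 was 582-fold (199 to 2823) and at least 986-fold higher. Cxcl9, a ligand of CXCR3, was at least 389-fold and at least 266-fold higher.

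Most genes of the transporter list and of the Wnt and identity list were lower under LPS in both genotypes. Of the 20 blood-brain barrier transporter genes, 18 were at least 2-fold lower in each genotype, with medians of -2.35 (-2.61 to -2.13) in wild type and -3.02 (-3.22 to -2.80) in knockout, below every one of 10000 random lists matched on expression. Slco1a4, an organic anion transporter, went from 2862 to 178 CPM and from 2541 to 149 CPM. Log2 folds were -3.79 and -2.95 for the large amino acid transporter Slc7a5, -4.24 and -3.09 for the monocarboxylate transporter Slc16a1 and -4.02 and -4.34 for the reelin receptor Lrp8. Bsg, the chaperone of monocarboxylate transporters, was 20.6-fold (18.7 to 22.6) lower in wild type and 82.0-fold (66.4 to 102) lower in knockout. The Wnt and identity list had medians of -2.06 (-2.25 to -1.84) and -2.07 (-2.29 to -1.85), below every one of the random lists, with 15 of 18 members in wild type and 13 in knockout at least 2-fold lower and 1 at least 2-fold higher in each. Its member Axin2, a Wnt target, had log2 folds of -2.87 and -2.79. The vesicular transport and fenestration list had medians of -1.75 (-1.99 to -1.44) and -1.14 (-1.61 to -0.72), at the 0.050 and 1.43 percentiles of random lists. Of its 9 compared members, 5 were at least 2-fold lower and 1 at least 2-fold higher in each genotype. Those lower included Cav1, the scaffold of caveolae, 21.5-fold (13.1 to 37.4) lower in wild type and 85.6-fold (29.0 to 418) lower in knockout, where 3 UMIs remained under LPS. Log2 folds were -5.13 and -5.81 for Cxcl12, a chemokine made by capillary endothelium, -4.58 and -4.97 for the actin-binding Ablim1, -4.37 and -4.84 for the neonatal Fc receptor Fcgrt and -4.30 and -4.05 for the scaffold Slc9a3r2. Under LPS, 7 and 2 UMIs remained of the sphingosine phosphatase Sgpp2 and 1 and 1 of Tril, against 208 and 233 and 84 and 89 under PBS. Markers of capillary cells stood at 10553 and 2669.6 CPM in wild type under PBS and LPS and at 9248 and 1547 CPM in knockout, and those of venous cells at 322, 298, 213 and 285 CPM. Markers of arterial cells went from 258 to 304 CPM in wild type and from 248 to 116 CPM in knockout. The capillary markers Mfsd2a, Slc16a1 and Tfrc and the venous marker Slc38a5 are also members of the transporter list, and Cxcl12 is a capillary marker. These levels are thus not separate from the folds above and cannot tell fewer capillary cells from lower expression of these genes.

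Junction genes were lower under LPS in wild type, while the direction of the knockout median depended on the scaling. The list median was -0.87 (-1.0 to -0.76) in wild type, at the 0.82 percentile of random lists, and -0.35 (-0.42 to -0.27) in knockout, at the 26.1 percentile, and the knockout value turned to 0.091 under median-of-ratios scaling, where wild type stayed at -0.46. Without the filter on low genes the knockout median was -0.090. Of the 14 compared members, 6 in wild type and 3 in knockout were at least 2-fold lower, and 1 was at least 2-fold higher in each. Cldn5 (ENSMUSG00000041378), the main claudin of brain endothelium, went from 4373 to 1406 CPM in wild type, a log2 fold of -1.63 (-1.72 to -1.55), and from 4614 to 3539 CPM in knockout, a log2 fold of -0.38 (-0.45 to -0.32) that turned to 0.064 under median-of-ratios scaling. Occludin (Ocln) had log2 folds of -1.96 and -2.02, the tricellular junction receptor Lsr -2.26 and -1.98, and plakoglobin (Jup) -3.31 and -3.04. VE-cadherin (Cdh5) was higher, with 1.77 and 1.66. The median difference of folds over the list was -0.32 (-0.54 to -0.15), with a more positive fold in knockout in 11 of 14 members. Excitatory neurons carried 0.274 to 1.11 CPM of Cldn5.

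Most genes of the angiopoietin and VEGF list were lower, with medians of -1.47 and -1.92. Of its 10 compared members, 7 in wild type and 8 in knockout were at least 2-fold lower and 1 at least 2-fold higher in each. Those lower included Kdr with -2.47 and -2.99, Tek with -2.78 and -3.55 and Nrp1 with -3.82 and -4.83, while Angpt2, the Tek antagonist stored in endothelial granules, was higher, with 3.97 and 5.73. The matrix and protease list had medians of 1.47 and 1.67, with log2 folds of 5.60 and 6.15 for the proteoglycan-cleaving protease Adamts9. Its relative Adamts4, with 1 UMI in each PBS library, was 123-fold (21.7 to 4866) higher in wild type and 460.2-fold (82.1 to 18221) higher in knockout. The coagulation list, with 5 compared members, stood at 0.75 and 1.62. Its member Plaur, the urokinase receptor, had 4.77 and 5.73, and thrombomodulin (Thbd) 1.46 and 1.62. List medians were 2.38 and 2.18 for glucocorticoid response, 0.69 and 1.09 for hypoxia and glycolysis, 1.05 and 1.25 for cell death, 0.32 and 0.71 for the unfolded protein response, and 1.03 and 0.72 for immediate early genes. The respiratory chain list had -0.90 and -0.79 and ribosomal proteins -0.51 and -0.36, the last turning to 0.085 under median-of-ratios scaling.

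The LPS co-receptor gene Cd14 and the cytosolic LPS sensor Casp4 were higher in both genotypes. The LPS sensing and pyroptosis list, with 7 compared members, had medians of 2.44 (1.69 to 3.35) and 2.25 (2.01 to 2.50). Casp4, which encodes mouse caspase-11, the protease that cleaves gasdermin D, went from 2 UMIs to 282 in wild type, 92.4-fold (25.3 to 767) higher, and from 2 to 97 in knockout, 56.6-fold (15.3 to 474) higher. Cd14 was at least 33.0-fold higher in wild type and 182-fold (32.2 to 7242) higher in knockout. Tlr4, the LPS receptor, had few UMIs, with 8, 24, 3 and 14 UMIs in wild type under PBS and LPS and knockout under PBS and LPS.

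**Figure D1:**
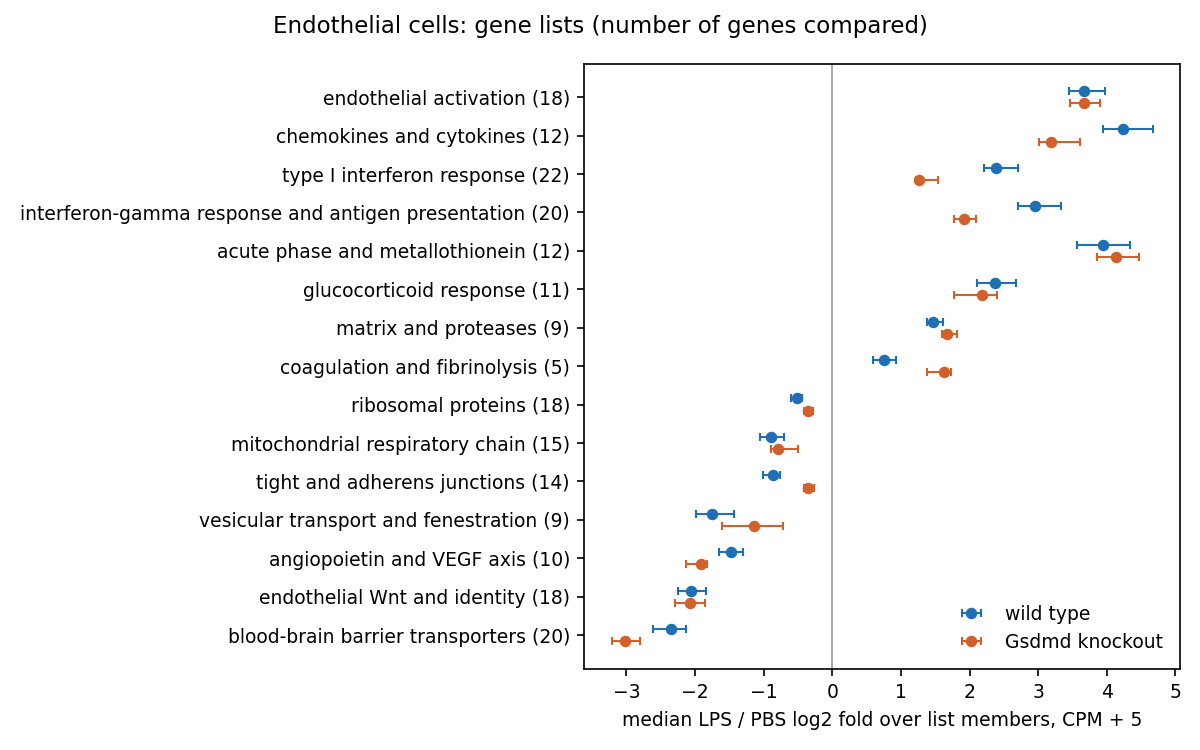
Median log2 fold of LPS over PBS (CPM + 5) for 15 gene lists in endothelial cells of wild-type (blue) and Gsdmd knockout (orange) mice, with the number of genes compared; bars are 95% intervals from Poisson redraws and cover counting error only. The endothelial activation list is at 3.67 in both genotypes, the type I interferon list at 2.38 and 1.26, and the tight and adherens junction list at -0.87 and -0.35, where the knockout value turned to 0.091 under median-of-ratios scaling, as that of the ribosomal protein list did to 0.085.

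Interferon-stimulated genes had the greater LPS response in the annotated endothelial cells of wild type. All 22 compared members of the type I interferon list had a greater log2 fold in wild type, with medians of 2.38 (2.21 to 2.71) and 1.26 (1.21 to 1.54) and a median difference of 0.74 (0.52 to 0.92), above every one of 10000 random lists. With members without UMIs under PBS at their bound the medians were again 2.38 and 1.26. The median difference was 0.43 with cells thinned to 1000 UMIs, and had a median of 0.83 over 40 redraws of the thinning. Of the 20 compared members of the interferon-gamma and antigen presentation list, 19 had a greater fold in wild type, with medians of 2.95 (2.70 to 3.33) and 1.92 (1.77 to 2.09). Rsad2, the antiviral viperin, reached 7055 CPM in wild type and 1247 CPM in knockout. The guanylate-binding proteins Gbp2 and Gbp5 had differences of 1.66 (1.20 to 2.17) and 1.44 (0.80 to 2.07). Cxcl10, an interferon-induced chemokine, reached 6998 CPM in wild type, 2567-fold (710.3 to 21198) above PBS, and 1032 CPM in knockout, where 30.7% of its UMIs came from 1 cell. Excitatory neurons of these libraries carried 12.6 and 5.64 CPM of Cxcl10. In the endothelial sums, markers of some other cell types were also higher under LPS in wild type and not in knockout, while those of pericytes, the contractile cells of capillaries, were lower in knockout and not in wild type. Pericyte markers went from 1147 to 1181 CPM in wild type and from 1934 to 1021 CPM in knockout. Oligodendrocyte markers went from 225 to 492 CPM in wild type and from 149 to 96.8 CPM in knockout, and inhibitory neuron markers from 50.4 to 189 CPM in wild type and from 42.5 to 25.5 CPM in knockout. Of neutrophil markers, 1 cell of the wild-type LPS library held 233 of 234 UMIs. Among genes eligible to be named, the 8 with the most positive differences were Cmpk2, Plscr2, Sp110, Dhx58, Mx1, Isg20, Fap and Serpinb6b. The difference was 2.86 (2.28 to 3.46) for the nucleotide kinase Cmpk2 and 2.83 (1.93 to 4.01) for the scramblase Plscr2. The others had 3 UMIs or fewer in at least 1 library. Under LPS the nuclear body protein Sp110 went from 2 to 222 UMIs in wild type and from 21 to 46 in knockout, and the RIG-I-like helicase Dhx58 from 0 to 107 UMIs in wild type and from 3 to 10 in knockout. The GTPase Mx1 went from 0 to 87 UMIs in wild type and from 0 to 4 in knockout, the exonuclease Isg20 from 2 to 478 UMIs in wild type and from 10 to 84 in knockout, and the protease Fap from 2 to 68 UMIs in wild type and from 6 to 6 in knockout. The serpin Serpinb6b went from 52 to 34 UMIs in wild type and from 66 to 0 in knockout, and with cells thinned to 1000 UMIs its difference of log2 folds turned from positive to -0.26. Il6 had 63 UMIs in wild type under LPS, 42.9% of them in 1 cell, and 1 UMI in knockout.

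Endothelial genes with the greater log2 fold in knockout were placental growth factor (Pgf), the stem cell factor receptor Kit, the folate enzyme Mthfd2 (-2.11, -3.19 to -1.05), the polymerase subunit Pola2 (-2.10, -3.18 to -1.09), the endothelial lectin Cd93 (-2.09, -2.34 to -1.84), Ctla2b (-1.90, -2.94 to -0.85), Rassf4 (-1.90, -2.99 to -0.79) and the fibronectin receptor subunit Itga5 (-1.89, -2.88 to -0.93). Pgf went from 2 to 9 UMIs in wild type and from 0 to 85 in knockout, and Kit from 9 to 134 UMIs in wild type and from 1 to 159 in knockout. Of the Pgf UMIs in knockout under LPS, 37.6% came from 1 cell. For the main lists, the median difference was 0.081 (-0.18 to 0.30) for endothelial activation, where 9 members had the greater fold in each genotype, and 0.25 (0.065 to 0.43) for transporters. With cells thinned to 1000 UMIs these were -0.23 and 0.57. These differences compare 4 libraries and were not tested.

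Endothelial cells of the genotypes were also compared directly. Under PBS the type I interferon list stood at a knockout over wild type median of 0.040 and the junction list at 0.13. Under LPS these were -0.71 and 0.40. Higher in knockout under both treatments were the transcription factor Sox18 (102 against 347 CPM under PBS), Atf4 (72.3 against 138 CPM), Gimap9 (5.45 against 17.4 CPM), Cd320 (40.9 against 84.0 CPM) and Mafg (43.6 against 82.9 CPM). Lower in knockout were Ifit2 (40.9 against 14.2 CPM under PBS), Oasl1 (17.7 against 6.54 CPM), Tor3a (28.6 against 12.0 CPM) and the clock repressors Nr1d1 (88.6 against 9.81 CPM) and Nr1d2 (54.5 against 22.9 CPM). Under LPS, Ifit2 stood at 1100 against 271 CPM, Nr1d1 at 47.4 against 8.91 CPM and Nr1d2 at 92.9 against 24.2 CPM. These genes are the extremes of a ranking and some had few UMIs. Under PBS, Ifit2 had 30 UMIs in wild type, 9 of them in 1 cell, and 13 in knockout.

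Homeostatic genes of microglia were lower and inflammatory genes higher under LPS in both genotypes. All but 3 of the 17 homeostatic genes in wild type, and all but 1 in knockout, were at least 2-fold lower, with medians of -2.08 (-2.13 to -2.02) and -3.01 (-3.30 to -2.74). Gpr34, a lysophosphatidylserine receptor, went from 990.3 to 11.1 CPM in wild type and from 1045 to 2.11 CPM in knockout, and the purine receptor P2ry12 had log2 folds of -3.57 and -4.72. Snx29 and Cd180 were also lower (-4.99 and -4.80, -4.92 and -4.55). The activated microglia list had medians of 2.81 (2.75 to 2.97) and 3.89 (3.74 to 4.01), or 3.06 and 3.89 with members without UMIs under PBS at their bound. The interleukin-12 subunit Il12b reached 6098 and 4827 CPM, Ccl5 2025 and 6418 CPM, and the interleukin-1 receptor antagonist Il1rn 988 and 2917 CPM. Ch25h was at least 621-fold and 1028-fold higher. Saa3, an acute phase protein, was 1129.5-fold (202 to 44639) higher in wild type and 4761-fold (1318 to 39317) higher in knockout, from 1 and 2 UMIs under PBS. The greater fold was in knockout also for AW112010 (-3.14, -3.73 to -2.62), and in wild type for Csrnp1 (3.54, 3.09 to 4.03) and the protocadherin Fat3 (3.44, 3.12 to 3.79). The type I interferon list had 2.09 in wild type and 3.45 in knockout. Oligodendrocyte markers in microglia stood at 322 CPM in wild type under PBS, 763 under LPS, and 187 and 148 CPM in knockout.

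Reactive astrocyte genes were higher under LPS in both genotypes, with greater medians in knockout. The pan-reactive list had medians of 2.78 (2.60 to 2.97) in wild type and 5.40 (5.29 to 5.50) in knockout, the LPS-type reactive list 2.68 and 6.05, and the type I interferon list 1.78 and 3.41, with a greater fold in knockout for all 11 compared members. Members below 50 CPM in every astrocyte library were not compared. With members without UMIs under PBS at their bound, the pan-reactive medians were 4.33 and 5.40 and the LPS-type medians 2.68 and 6.88. Gfap, the intermediate filament of reactive astrocytes, reached 377 and 804 CPM, from 29.9 and 9.94 CPM. The serpin Serpina3n had log2 folds of 5.49 and 5.89, the cytokine receptor Osmr 5.20 and 6.16, the GTPase Irgm1 5.49 and 5.89 and the glucocorticoid target Fkbp5 6.94 and 6.88. Lower were the Notch target Hes5 (-3.94 and -3.39), the laminin Lama3 (-3.25 and -4.72) and St6galnac5 (-2.90 and -3.50). Ptx3 (-4.02, -4.55 to -3.58) and Trim47 (-2.98, -3.57 to -2.50) had the greater fold in knockout, Epb41l4a (2.89, 2.57 to 3.20) and Arhgef28 (2.67, 2.35 to 2.98) in wild type. The homeostasis and end-foot list was near 0, with -0.11 and 0.038, the last turning to -0.024 under median-of-ratios scaling. The wild-type LPS library held 107 astrocytes, whose oligodendrocyte markers stood at 1624 CPM, against 200.5, 95.8 and 103 CPM in wild type under PBS and knockout under PBS and LPS. In the wild-type LPS library 1440 of 3421 of these UMIs came from 1 cell, and the level without it was 962 CPM. The myelin list in astrocytes was 2.62 in wild type and 0.048 in knockout.

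**Figure D2:**
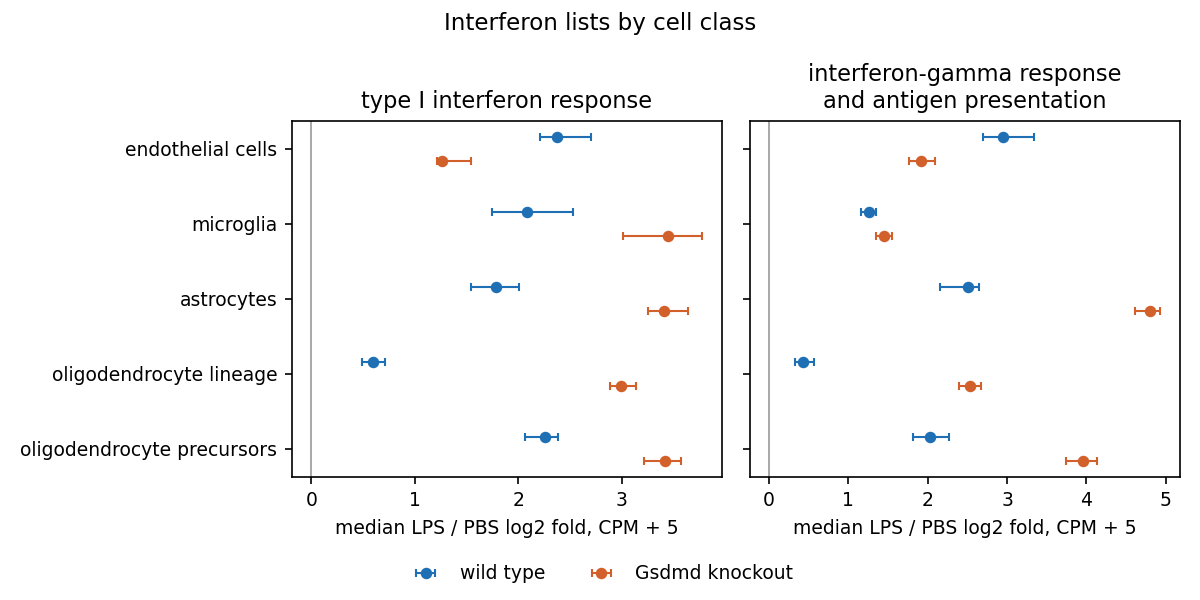
Median log2 fold of LPS over PBS (CPM + 5) of the type I interferon list and the interferon-gamma and antigen presentation list in the 5 non-neuronal classes, wild type in blue and Gsdmd knockout in orange; bars are 95% intervals from Poisson redraws and cover counting error only. Over the members compared in each class, endothelial cells have the greater median in wild type for both lists (2.38 against 1.26 and 2.95 against 1.92), and the other classes have it in knockout.

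Stress genes were higher under LPS in cells of the oligodendrocyte lineage. The oligodendrocyte stress list had medians of 2.81 (2.77 to 2.87) and 3.19 (3.12 to 3.29), with members such as the cell cycle inhibitor Cdkn1a (5.43 and 6.86) and the lipid droplet protein Plin4 (4.33 and 4.54). Rhoj (4.62 and 4.75) and Tma16 (4.52 and 4.27) were also higher, and Fbn2 (-2.45 and -3.56), Pik3c2b (-2.28 and -2.90) and Rnf220 (-2.27 and -2.39) lower. Myelin genes stayed close to 0 (0.17 and -0.018). The type I interferon list had 0.60 in wild type and 2.99 in knockout, over 6 members. Jph4 (2.17, 2.01 to 2.33) and Spock1 (2.05, 1.97 to 2.13) had the greater fold in wild type, Mgp (-3.76, -4.01 to -3.52) and Ppfibp1 (-3.13, -3.34 to -2.93) in knockout. Committed precursors made up 104, 6, 58 and 52 of the cells of this class, so its makeup differed between libraries. Markers of oligodendrocyte precursors in this class went from 451 to 95.6 CPM in wild type and from 611 to 954 CPM in knockout, and inhibitory neuron markers from 34.6 to 105 CPM in wild type and from 22.3 to 32.8 CPM in knockout. Oligodendrocyte precursors had higher Cebpd (4.56 and 6.00), Irf1 (4.37 and 4.79) and Irgm1 (4.77 and 5.41), and lower Hes5 (-3.37 and -4.02), Lypd6 (-2.97 and -3.22) and Gpr17 (-2.25 and -3.74). Their monocyte chemokine Ccl2 reached 322 CPM in wild type and 2544 CPM in knockout. The type I interferon list was 2.26 and 3.42, or 2.48 and 3.42 at the bounds. In the precursor sums, microglia markers went from 60.2 to 145 CPM in wild type and from 76.3 to 151 CPM in knockout, with 142 of 530 and 166 of 712 UMIs of the LPS libraries in 1 cell each. Endothelial markers went from 12.7 to 24.4 CPM in wild type and from 10.6 to 64.1 CPM in knockout, with 165 of 303 UMIs of the knockout LPS library in 1 cell. Hpgd (-2.60, -3.07 to -2.13) had the greater fold in knockout, Tmem120b (2.48, 1.98 to 3.02) and Morn3 (1.82, 1.33 to 2.35) in wild type.

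Folds in neurons were smaller than in the other classes. In excitatory neurons the activity-regulated Arc and Bdnf were lower (-1.52 and -1.74, -1.28 and -1.21), as was Scube1 (-1.09 and -1.14), and Dbp (1.52 and 1.60), the cold-inducible Cirbp (1.43 and 1.36), Zbtb7c (1.27 and 1.71) and Wipf3 (1.15 and 1.43) higher. The noncoding Bc1 (1.87, 1.80 to 1.94) and AY036118 (1.44, 1.42 to 1.47) had the greater fold in wild type, Cdh7 (-1.18, -1.25 to -1.12) and Syt17 (-1.13, -1.19 to -1.05) in knockout. The makeup of this class differed between libraries. It held 4075, 1748, 3541 and 4711 cells in wild type under PBS and LPS and knockout under PBS and LPS. Of these, 877, 253, 543 and 986 were layer 2/3 cells and 788, 314, 1032 and 920 layer 6 corticothalamic cells. In the excitatory neuron sums, inhibitory neuron markers went from 18.0 to 97.2 CPM in wild type and from 17.5 to 19.6 CPM in knockout, and oligodendrocyte markers from 106 to 280.5 CPM in wild type and from 90.2 to 90.5 CPM in knockout. In the inhibitory neuron sums oligodendrocyte markers went from 181 to 294 CPM in wild type and from 126 to 80.3 CPM in knockout, where 821 of 2255 UMIs under PBS came from 1 cell and the level without it was 80.1 CPM. In inhibitory neurons Klf9 (1.14 and 0.75), Cirbp (1.07 and 1.24), Galnt17 (0.89 and 0.76) and Hrh3 (0.97 and 0.74) were higher and Zfp804a (-1.21 and -1.27), Fam46a (-1.14 and -0.98) and Egfr (-1.43 and -0.84) lower. The neuropeptide gene Npy (-1.73, -1.76 to -1.71) and Yjefn3 (-1.06, -1.20 to -0.93) had the greater fold in knockout, Cmss1 (1.28, 1.24 to 1.33) and Pvalb (1.27, 1.13 to 1.40) in wild type. In cells of 1000 to 40000 UMIs the Yjefn3 difference turned to 0.72 and the wild-type Pvalb fold to -0.039, from 1.59. With every class sampled to 733522 UMIs per library, the 90th percentile of the absolute log2 fold was 2.35 and 2.40 in endothelial cells of wild type and knockout, 2.30 and 2.53 in microglia, 1.57 and 1.86 in astrocytes, 1.22 and 1.40 in oligodendrocyte precursors, 1.21 and 1.20 in the oligodendrocyte lineage, 0.65 and 0.65 in excitatory neurons and 0.61 and 0.55 in inhibitory neurons. Counting error alone gave 0.40 to 0.44.

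Class shares differed between the 4 libraries. Endothelial cells were 0.869% (0.668 to 1.11), 2.51% (2.05 to 3.05), 1.68% (1.36 to 2.06) and 0.760% (0.566 to 0.998) of annotated cells in wild type under PBS, wild type under LPS, knockout under PBS and knockout under LPS, with exact Clopper-Pearson intervals. Astrocytes were 11.2%, 2.72%, 9.32% and 9.01%, microglia 4.23%, 8.43%, 2.93% and 2.58%, and inhibitory neurons 12.6%, 24.6%, 8.59% and 7.18%. Cells were dissociated and sorted before loading, which can set such shares. Barcodes without annotation can set them too. In a count chosen after seeing the data, annotated endothelial cells and barcodes without annotation that carried endothelial markers made up 1.04% (0.845 to 1.27), 2.05% (1.74 to 2.41), 2.48% (2.15 to 2.84) and 2.23% (1.94 to 2.56) of all barcodes in the 4 libraries in the same order, with overlapping intervals in knockout. The same count for astrocytes gave 15.0%, 12.7%, 10.5% and 9.92%, at a marker threshold that 13.7%, 7.75%, 11.7% and 4.45% of annotated cells of other classes also reached.

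**Figure D3:**
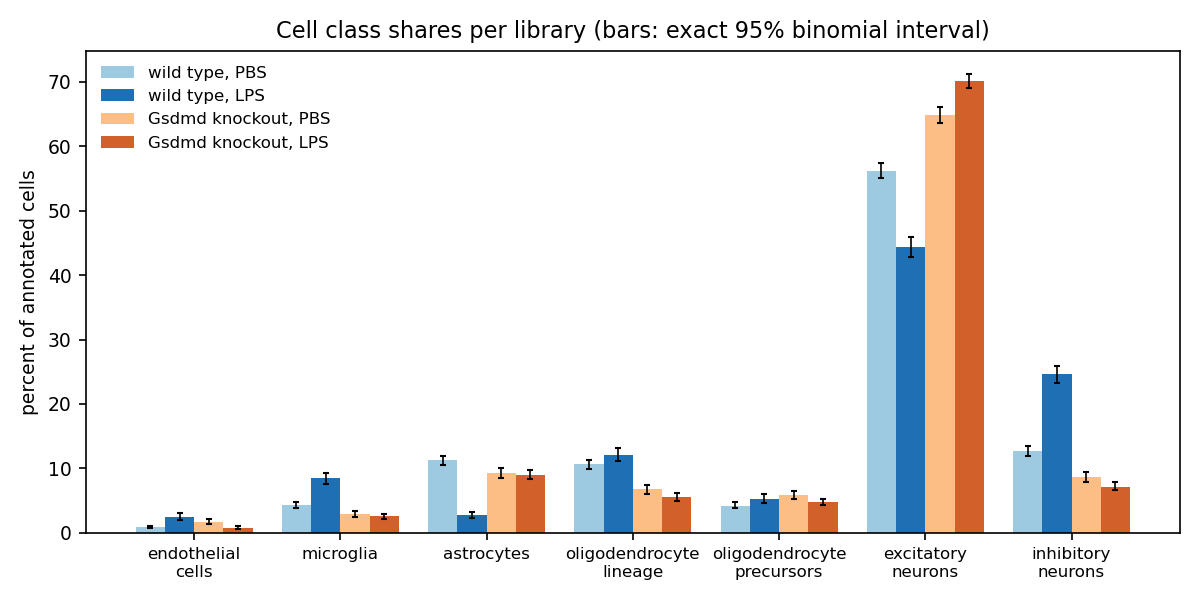
Percent of annotated cells in each of the 7 classes for the 4 libraries, with exact 95% binomial intervals. Astrocytes are 2.72% of the wild-type LPS library and 9.01% to 11.2% of the others.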

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

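The check of endothelial markers in barcodes without annotation was chosen after the main results were seen. In microglia, 3 named genes had LPS log2 folds of opposite sign in the genotypes, and the differences were not tested, since each group is 1 library. Csrnp1, an AP-1 related transcription factor, was higher under LPS in wild type (2.04) and lower in knockout (-1.50), a difference of 3.54, with 87, 607, 128 and 51 UMIs in wild type under PBS and LPS and knockout under PBS and LPS. Bcl2l11, which encodes the apoptosis activator BIM, had log2 folds of 1.04 and -1.24, a difference of 2.28, with 170, 554, 184 and 94 UMIs. Cldn11, a claudin of myelin and a marker of oligodendrocytes, had log2 folds of 1.15 and -1.40, a difference of 2.55, with 61, 231, 60 and 22 UMIs. Oligodendrocyte markers as a whole stood highest in the microglia of the wild-type LPS library.

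Among barcodes that the authors left without annotation, those with endothelial markers made up 6.56% (150 of 2288) in knockout under LPS and 4.17% (106 of 2540) in knockout under PBS. In wild type the shares were 1.49% (48 of 3219) under LPS and 1.61% (35 of 2179) under PBS. The knockout matrices hold exactly 8000 barcodes under PBS and 9000 under LPS, and the cell calling settings are not given in the sources used here. The number of barcodes called sets the denominators of these shares. These barcodes enter no comparison of expression, and the difference was not tested.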

How the results depend on the processing

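Over 2308 results, 21299 values under alternatives were computed, of which 17109 stayed within the counting interval, 4152 moved beyond it and 38 changed the sign of a log2 value of at least 1. Of 10013 alternative values of results of at least 2-fold, 9944 kept the sign, 38 took the opposite sign and 31 were exactly 0. With cells thinned to 1000 UMIs, those at 0 included the knockout endothelial folds of Sele, Mx1 and Tor3a. Some outcomes in these counts were fixed in advance. Dropping the filter on low genes leaves every single-gene value as it was. A pseudocount of 1 CPM cannot turn the sign of a single-gene fold of LPS over PBS. Many of the genes were also named for large folds in the same data, so the counts overstate how stable the results are. The alternatives without the top cell of each gene, without cells richer in another class's markers, without the committed precursor or layer 6 corticothalamic subtype, and over all barcodes were chosen after seeing the data. Leaving out those subtypes moved 112 of the values of the oligodendrocyte lineage, where 195 stayed within the interval, and 100 of those of excitatory neurons, where 99 stayed. It turned no log2 value of at least 1, the only values for which a change of sign was counted. Depth limits the thinned values, since 51 to 99 endothelial cells at 1000 UMIs leave few counts per gene. Where no cause is named below, the cause was not tested.

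In endothelial cells, median-of-ratios scaling gave activation medians of 4.04 in wild type and 4.10 in knockout, junction medians of -0.46 and 0.091, and transporter medians of -1.95 and -2.58, since it rescales each library by a single factor. A pseudocount of 1 CPM, which shrinks low genes less, gave activation medians of 4.19 and 4.31, a difference of 0.33 and an r between genotypes of 0.876. Without the filter on low genes, activation in knockout was 3.40, junctions -0.74 and -0.090, the pericyte list in knockout -0.086 and r 0.764. The mean of CPM per cell gave r 0.867. Thinning gave an activation difference of -0.23, a junction median of -0.71 in wild type, a transporter difference of 0.57, r 0.605, and differences of -0.20 for Cd274, -0.83 for Cav1 and -0.26 for Serpinb6b. The size of the endothelial response was 2.09 in wild type and 2.20 in knockout at 20 CPM, and 3.12 and 3.15 at 200 CPM.

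In microglia, no filter on low genes gave 0.0023 for vesicular transport in wild type and a pan-reactive list difference of 0.24. Thinning gave differences of -0.23 for the coagulation list and for F3, 0.21 for Ifitm3, -0.044 for Gbp5, -1.35 for Klf9 and -0.23 for Slc1a2, and a knockout fold of 0.23 for Pdk1. Without cells richer in another class's markers, the coagulation list and F3 differed by -0.23, and Slc1a2 was 0.34 in knockout with a difference of -0.32. In astrocytes, no filter on low genes gave homeostatic microglia medians of -0.00093 and -0.070 and a pericyte list difference of 0.13. In oligodendrocyte precursors, thinning gave differences of 0.061 for Ier3 and 0.066 for Serpina3n. In inhibitory neurons, cells of 1000 to 40000 UMIs gave -0.039 for Pvalb in wild type, -0.051 for Yjefn3 in knockout and a Yjefn3 difference of 0.72, and thinning 0.60.

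Leaving out cells with 3 or more UMIs of other classes' markers kept 12, 2, 11 and 9 cells of the 4 libraries, and 3, 2, 2 and 1 of the oligodendrocyte lineage, so its knockout LPS values rest on 1 cell. It was not run for folds in classes other than the oligodendrocyte lineage, nor were capillary cells compared alone, since the annotation does not divide endothelial cells. In that lineage it gave -3.25 for the chemokine list, Csf1 and Adamts1 in knockout, 1.46 for Adamts4 in knockout, and -0.60 for Csf1, -3.75 for Reck and 0.33 for Eno1 in wild type. Differences were 0.32 for Mt2, 0.086 for Cdkn1a, 0.089 for Eno1, 0.68 for Ldha and -2.01 for Fbn2. Its endothelial shares were 8.33%, 0%, 18.2% and 0% in wild type under PBS and LPS and knockout under PBS and LPS, and its astrocyte shares 66.7%, 0%, 63.6% and 77.8%. Cells of 1000 to 40000 UMIs gave endothelial shares of 1.31%, 4.51%, 2.86% and 1.55% and astrocyte shares of 16.9%, 4.78%, 15.7% and 18.2%, since this filter removes mostly neurons. Over all barcodes, with those of a class's markers and no annotation, endothelial shares were 2.48% and 2.23% in knockout under PBS and LPS, and astrocyte shares 15.0%, 12.7%, 10.5% and 9.92%.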

Other observations

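The test of depth per cell for the interferon pattern was written before its result was seen, its 40 redraws were added after the first thinned value was seen, and all other tests here were chosen after the result was seen. Most compared members of the glucocorticoid response list were at least 2-fold higher under LPS in 4 classes, 8 and 8 of 11 in endothelial cells of wild type and knockout, 8 and 8 of 9 in the oligodendrocyte lineage, 9 and 11 of 12 in astrocytes and 5 and 5 of 8 in oligodendrocyte precursors. Medians in these classes lay at the 99.97 percentile of random lists or higher. They were 2.81 (2.76 to 2.87) and 3.01 (2.91 to 3.11) in the oligodendrocyte lineage of wild type and knockout, 2.05 and 2.08 in astrocytes and 1.94 and 1.92 in oligodendrocyte precursors. Medians were 0.84 and 0.48 in excitatory and 0.60 and 0.29 in inhibitory neurons. Microglia had 0.34 and -0.090, the last turning to 0.13 under median-of-ratios scaling. The immediate early gene list had medians of 2.18 and 3.33 in astrocytes, where 11 and 12 of 12 compared members were at least 2-fold higher. In microglia the medians were -0.80 and -1.72, with 8 and 12 of 17 members at least 2-fold lower and 3 and 1 at least 2-fold higher. In excitatory neurons they were -0.55 and -0.31, with 2 and 3 of 7 members at least 2-fold lower.

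Clock genes were listed after Nr1d1 was seen among the endothelial genes. In endothelial cells Nr1d1, a repressor of the core clock, had 65, 53, 9 and 7 UMIs in wild type under PBS and LPS and knockout under PBS and LPS, a knockout over wild type log2 fold of -2.66 under PBS and -1.91 under LPS. In excitatory neurons, with 5745 UMIs or more per library, these folds were -0.035 and -0.44. They were -0.71 and -0.56 in the oligodendrocyte lineage, -0.39 and -0.55 in oligodendrocyte precursors and -0.41 and 0.41 in astrocytes. Microglia had -0.24 and -0.90 and inhibitory neurons 0.030 and -0.28. Endothelial folds were -1.09 and -1.75 for Nr1d2, -1.25 and -1.02 for Tef, -0.22 and -0.67 for Per1 and -0.67 and -0.38 for Per3, and 0.26 and 0.62 for Arntl, the activator that Nr1d1 represses. The other listed genes had -0.33 and -0.76 (Dbp), -0.35 and -0.99 (Per2), 0.56 and -1.17 (Ciart) and 0 and -0.46 (Bhlhe41). Several rest on few UMIs, with 24, 26, 10 and 7 for Tef, 20, 11, 14 and 5 for Per3 and 1, 36, 4 and 9 for Ciart. Nr1d2 had -0.70 and -0.87 in the oligodendrocyte lineage. In excitatory neurons Per1 had 0.81 and -0.11 and Per2 0.61 and 0.40.

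The type I interferon list had the greater LPS fold in wild type in endothelial cells and in knockout in astrocytes, microglia, the oligodendrocyte lineage and its precursors. Only members that reached 50 CPM in at least 1 library of a class were compared. The filter can thus favour the library where members are high. Ifit2, below that level, went from 6.40 to 6.59 CPM and from 10.2 to 9.80 CPM in the oligodendrocyte lineage of wild type and knockout. In microglia it went from 13.9 to 12.6 and from 3.27 to 4.22 CPM. In astrocytes the values were 1.03 to 5.70 and 1.04 to 34.9 CPM. Against free RNA from other cells, compared members of the list stood at a median of 47.3 times the level of excitatory neurons in the wild-type LPS endothelial cells. Free RNA alone would also give a ratio above 1, since endothelial cells there had a median of 9088 UMIs and excitatory neurons 50611. The members compared were those that reached 50 CPM in an endothelial library, which can raise the ratio. Against a single cell per gene, the endothelial difference was 0.76 without the top cell of each gene. Only 1 cell was left out for each gene, so this cannot decide whether several cells carry the difference. Against dilution of the wild-type astrocyte RNA, the astrocyte homeostasis list had a difference of 0.083, where dilution needs about that of the interferon list, -1.59. Depth per cell stays open, since cells thinned to 1000 UMIs gave 0.43, and 40 redraws of the thinning a median of 0.83 with 95% of them between 0.31 and 1.36, while the mean of CPM per cell gave 0.73. The choice of cells by annotation stays open too and was not tested. In knockout under LPS, 150 barcodes without annotation reached the endothelial marker threshold, beside 51 annotated endothelial cells. In wild type under LPS these were 48 and 99. An effect of genotype also stays open and was not tested, since genotype is confounded with library.

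Gm10600, a gene model on chromosome 4 from 42240639 to 42242685, lies outside the rule for named genes and was chosen after its values were seen. It was near 0 in both knockout libraries. Excitatory neurons held 18278 and 4 UMIs in wild type and knockout under PBS and 9436 and 12 under LPS. Against lower depth of the knockout libraries, their excitatory neurons held 0.948 times the wild-type UMIs under PBS and 2.74 times under LPS, and against DNA linked to Gsdmd, the gene lies on chromosome 4 and Gsdmd on chromosome 15. A scan sought genes at least 4-fold apart between the genotypes in the same direction under PBS and LPS. It asked for this in every class where the gene reached 50 CPM in at least 1 library. Gm10600 was the only gene found, over 2 classes. Smaller differences, or those limited to some of these classes, are not covered by the scan. A hypothesis is that the mice may differ in strain background apart from the Gsdmd locus, which was not tested.

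The wild-type LPS library held the fewest annotated astrocytes of the 4. Loss of astrocytes to the authors' cell filter stays open, since the test turned with the marker threshold. At the 5th percentile of annotated astrocytes, the share of all barcodes was 2.14% against 10.2% in wild type under PBS, a ratio of 0.21 (0.176 to 0.250), and at 20 marker UMIs per 10000 with annotated astrocytes it was 12.7% against 15.0%, a ratio of 0.845 (0.777 to 0.919). The looser threshold also takes in 7.75% of annotated cells of other classes in that library and 13.7% in wild type under PBS, and of its barcodes without annotation 592 of 800 (74.0%) and 271 of 600 (45.2%) lay above the highest mitochondrial share of any annotated cell of their library. Dissociation and sorting of 1 library also stay open, as does an effect of LPS in wild type, which was not tested.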
